A study of Mus musculus with 25 samples.

How the data were processed

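Airway epithelial cells of mice, grown on a support with air above and medium below, were profiled on 25 Affymetrix Mouse Genome 430 2.0 arrays. The cells were wild type (WT) or came from mice lacking Mmp7 (Mmp7KO) or Mmp10 (Mmp10KO). They were uninfected (0 h) or had been given Pseudomonas aeruginosa at a multiplicity of infection of 5 for 1 h or 24 h. Each of the 9 groups of genotype and time holds 3 arrays, except WT at 24 h (replicates 2 and 3) and Mmp10KO at 24 h (replicates 1 and 3), which hold 2. The number of arrays limits the precision. The labels do not say whether replicates came from separate animals or cultures, so p-values measure the spread between samples. The authors' values came from GCOS and RMA per the submitters' processing notes, with no versions given.

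The deposited values are on the log2 scale and are centred. In each genotype the values of all 45101 probe sets average to 0 over the arrays of that genotype (within 1e-06). The log base was read from the values: the widest range of a probe set within a genotype, 11.3, exceeds 11.1, the natural log of the scanner's maximum. Because of the centring, absolute levels and constant differences between genotypes cannot be recovered. Of the 21 contrasts planned, 12 could be estimated: the responses at 1 h and 24 h within each genotype, and the differences between those responses. The 9 contrasts of genotypes at a single time could not.

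Probe sets were named from a table supplied beside the values. Of the 45101 probe sets, 35890 were listed and 34945 of these named a single gene, while 932 named several genes and 9211 were not listed. 64 control probe sets were left out. The gene IDs of 34754 probe sets matched a RefSeq gene table (assembly GRCm38.p6), which served only for symbols and for which genes neighbour each other. The remaining probe sets gave 18193 genes, of which 9010 had several probe sets. The planned rule, that the probe set with the highest mean stands for its gene, needs absolute levels, so the mean of a gene's probe sets was used in its place. For the same reason neither a filter on dim genes nor a variance trend with intensity could be applied.

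Responses were fitted with limma 3.58.1 (lmFit and eBayes, in R 4.3.3) in one model of the 9 groups, with 16 residual degrees of freedom and a prior of 4.52. Values of the fit are log2 changes ± standard error (SE), and limma's moderated test was two-sided. P-values were adjusted by the Benjamini-Hochberg method over all 18193 genes in each contrast, and a gene was called at an adjusted p under 0.05. A response difference is the log2 response of the genotype named before "against" minus that of the genotype named after it, tested as an interaction contrast. The median SE over genes was 0.112 for 1 h responses and the Mmp7KO 24 h response, 0.126 for the other 24 h responses, 0.159 for 1 h differences, and 0.169 or 0.178 for 24 h differences. The spread of a gene is pooled over the 9 groups, so an SE does not show how far the arrays compared differ. Over probe sets, the SD of the difference between the 2 arrays was 0.48 in Mmp10KO at 24 h and 0.32 in WT at 24 h. The SE and p-values of Mmp10KO at 24 h can thus understate the spread of its arrays.

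31 gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a contrast, and again with a correlation estimated from the data. Members were also counted when adjusted over the list alone. Genes on chromosome 9 near Mmp7 and Mmp10 were compared with other genes by a two-sided Fisher's exact test. The gene lists, contrasts, tests, threshold, most alternatives and the rule for named genes were fixed before the data were examined. That rule names Mmp7 and Mmp10 in every contrast and, among called genes whose groups' arrays do not overlap, the 8 largest changes each way for the WT responses and the 24 h responses of the knockouts, or the 4 largest each way elsewhere. Overlap was not asked of response differences, and placeholder symbols were left out. It adds up to 4 members with the lowest adjusted p from each list described, 12 fixed inflammatory genes wherever that list is described, and called genes of the chromosome 9 list. Members outside the rule were named where 5 or fewer moved one way, and are given as chosen after their values were seen.

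The pipeline was tested on simulated data for 6 contrasts, in each of which 67 genes were changed by 1.5-fold, 67 by 2-fold and 66 by 4-fold among 18193. The noise was normal and independent between genes, with 1 SD per gene for all arrays. In the real data the residual SD ran from 0.077 (Mmp7KO_1h replicate 1) to 0.258 (Mmp10KO_1h replicate 1). The rates below therefore leave out unequal arrays and correlated genes. For the WT 1 h response it recovered 71.6% of the 1.5-fold and 98.5% of the 2-fold genes, with 7 false calls. For the WT 24 h response these were 70.1% and 91.0%, with 6, for that of Mmp7KO 67.2% and 94.0%, with 7, and for that of Mmp10KO 59.7% and 94.0%, with 12. For the 24 h difference between Mmp7KO and WT they were 32.8% and 82.1%, with 3, and for that between Mmp10KO and WT 19.4% and 68.7%, with 6. Random draws used the seed 20, and simulated overlaps used 100 draws.

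Alternatives fixed beforehand were repeat quantile normalization, a shift of each array to the same median, array weights, a fit of the compared groups alone, the replicate number as a block, a minimum fold of 1.5, each probe set on its own, leaving out each array in turn, and the estimated correlation. 5 alternatives were added after seeing the data: the probe set with the largest spread for each gene, a robust prior, leaving out both arrays with the highest 18S ribosomal RNA signal, that signal as a covariate, and the difference of the 3 prime and 5 prime control probe sets as a covariate. The repeat quantile normalization acted on values already centred within genotype, so it also evened out the spread of the responses between arrays. Python 3.11.15 and matplotlib 3.10.9 drew the plots.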

Results

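Transcripts of 18193 genes were measured in airway epithelial cells of WT, Mmp7KO and Mmp10KO mice, uninfected or at 1 h or 24 h after P. aeruginosa, a bacterium that infects damaged airways. Mmp7 and Mmp10 encode matrilysin and stromelysin-2, secreted metalloproteinases. The comparisons ask how the epithelium responds to the bacterium and whether the response depends on either enzyme. Only 0 h cultures were uninfected, so infection cannot be separated from handling or time at 1 or 24 h. The largest component of variation (57.2% of the variance) placed the 24 h arrays at scores of 23.2 to 52.3 and all other arrays at 4.22 or below. Mmp10KO_24h replicate 1 had the lowest score of the 24 h arrays, and its partner, replicate 3, scored 49.0. The 18S ribosomal RNA probe sets stood 3.81 log2 units above the Mmp10KO mean in Mmp10KO_1h replicate 1 and 2.81 above it in Mmp10KO_24h replicate 3. In the 6 responses, each gene named as rising or falling had no overlap between the arrays compared. Chance gives this to 10% of genes for 3 against 3 arrays and to 20% for 3 against 2.

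**Figure D1:**
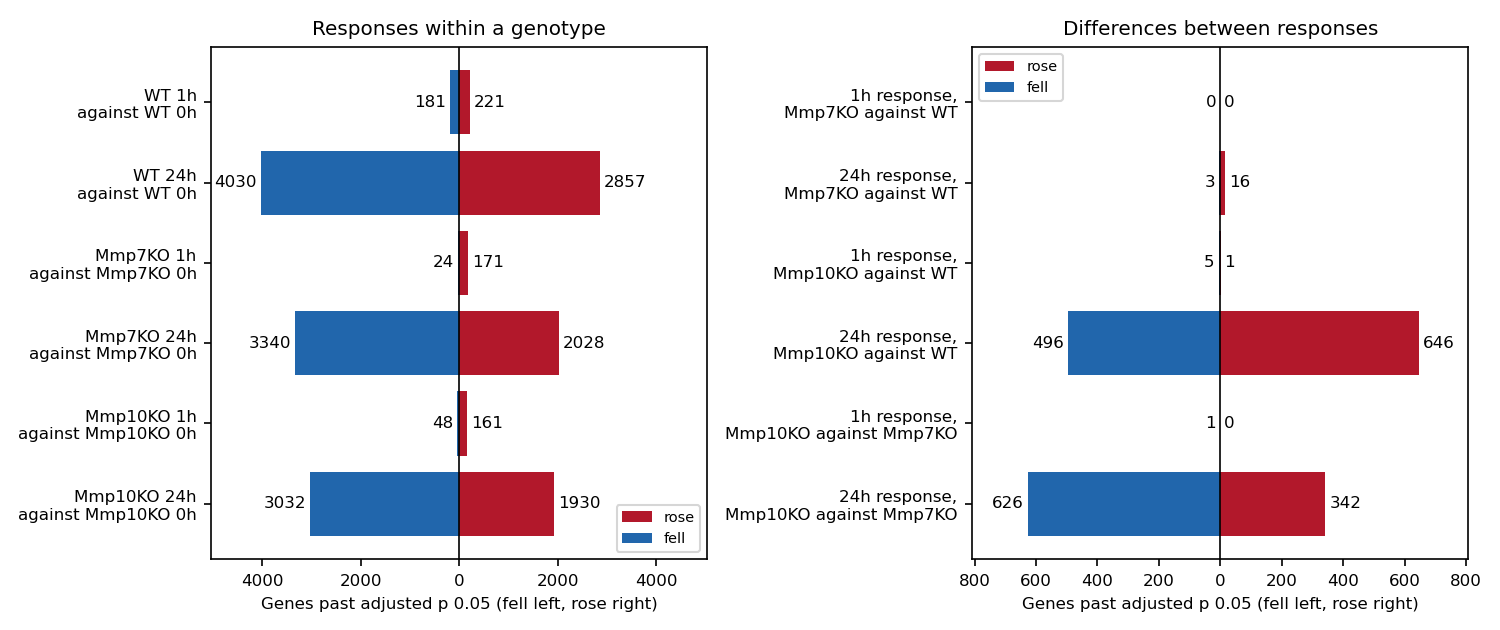
Genes past an adjusted p of 0.05 in each contrast (x axis, number of genes, fell to the left and rose to the right), for the 6 responses (left) and the 6 differences between responses (right, another scale). The 24 h responses moved 4962 to 6887 genes and the 1 h responses 195 to 402, while the differences ranged from 0 genes to 1142.

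At 1 h, WT cells raised chemokines and immediate early genes. Cxcl2, which attracts neutrophils, rose 240-fold (log2 7.91 ± 0.31 SE, n = 3 and 3), and the related Cxcl1 rose 57.8-fold (5.85 ± 0.30). Ccl20, which attracts dendritic cells and lymphocytes, rose 46.1-fold (5.53 ± 0.47). The transcription factors Atf3 (6.63 ± 0.34), Nr4a1 (6.21 ± 0.21), Fosb (5.87 ± 0.15) and Egr2 (5.28 ± 0.19) rose, as did Dusp1, a phosphatase of MAP kinases (5.56 ± 0.30). The largest falls were of the zinc finger genes Zfp866 (-1.75 ± 0.23), Zfp551 (-1.60 ± 0.12), Zfp748 (-1.44 ± 0.17) and Zfp119b (-1.17 ± 0.21), the C-type lectin Clec2d (-1.26 ± 0.21), Gdap10 (-1.18 ± 0.20), the small nucleolar RNA Snord104 (-1.13 ± 0.16) and the histone gene H3f3b (-1.11 ± 0.15). Of 18193 genes, 221 rose and 181 fell, and 112 of the rises and 17 of the falls reached 2-fold. Falls outnumbered rises in other settings: 299 rose and 335 fell after quantile normalization, 376 and 408 with array weights, 319 and 560 with the 18S covariate, 303 and 412 without both arrays of high 18S, 194 and 199 with the largest-spread probe set, 364 and 426 with each probe set on its own, and 236 and 249 without WT_1h replicate 1. Without WT_1h replicate 3 the 402 calls became 218, of which 48 fell, and without WT_0h replicates 1 or 2 they became 246 and 257.

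Among the lists at 1 h in WT, 31 of 38 immediate early genes rose, 1 fell and 6 did not pass (35 and 1 adjusted over the list alone, median 2.43, camera adjusted p = 4.18e-104, adjusted p = 4.48e-05 with an estimated correlation). Fos rose by 4.96 and Egr1 by 4.76, while Hes1, a Notch target chosen after its values were seen, fell by 0.48. Of 30 inflammatory cytokines and chemokines 10 rose and 20 did not pass (15 adjusted over the list alone, camera adjusted p = 2.45e-21, adjusted p = 0.00104 with an estimated correlation). Tnf rose by 3.18, Lif by 3.14, Csf3, the neutrophil growth factor, by 3.57, and Il6 by 1.14. The acute phase and antimicrobial genes Lcn2 (0.24), Saa3 (2.17) and S100a8 (0.09) did not pass. In the NF-kB pathway, 12 of 29 genes rose, with 18 adjusted over the list alone (camera adjusted p = 5.54e-28, adjusted p = 8.53e-06 with an estimated correlation), among them the feedback inhibitors Tnfaip3 (4.29) and Nfkbia (2.77), Nfkbiz (3.52) and the adhesion molecule Icam1 (1.73).

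Wound genes moved with these: 5 of 25 squamous and wound response genes rose at 1 h in WT, with 7 adjusted over the list alone (camera adjusted p = 1.92e-10, adjusted p = 0.0389 with an estimated correlation). They were the growth factors Hbegf (4.97) and Ereg (3.55), the plasminogen system genes Plaur (2.84) and Plat (0.98), and Serpinb2 (0.55), chosen after its values were seen. Of 29 metalloproteinases and inhibitors, Mmp13 (1.18), Timp3 (2.14-fold) and Adamts1 (0.56) rose and 26 did not pass, Mmp3 (0.24) among them, with 3 adjusted over the list alone (camera adjusted p = 0.00171, adjusted p = 0.0810 with an estimated correlation). Of 31 mucosal antimicrobial genes, Cfb, of the complement pathway (2.38), and the protease inhibitor Slpi (0.65) rose and 29 did not pass, with 4 adjusted over the list alone (camera adjusted p = 0.000163, adjusted p = 0.224 with an estimated correlation). None of 24 leukocyte markers passed limma's test, or adjusted over the list alone, with Csf3r at 0.31, Coro1a at 0.27 and Cxcr2 at 0.26 (camera adjusted p = 0.00105, adjusted p = 0.472 with an estimated correlation). Without WT_1h replicate 3, the calls of Mmp13 (0.88, adjusted p = 0.380), Timp3 (0.98, 0.180), Adamts1 (0.53, 0.0695), Cfb (1.80, 0.208) and Slpi (0.53, 0.178) ended, and so did that of Serpinb2 without WT_0h replicate 3 (0.41, 0.268). Mmp13 and Serpinb2 lost the call in 17 and 15 of the 25 fits that left out 1 array, and Il6 in 10, its highest adjusted p being 0.154 (0.99) without WT_1h replicate 2.

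By 24 h, 6887 genes had changed in WT, 2857 up and 4030 down. Cxcl2 stood 339-fold above 0 h (log2 8.40 ± 0.34 SE, n = 3 and 2), Csf3 94.1-fold (6.56 ± 0.27) and Ccl20 at 6.37 ± 0.52. Other large rises were of the neutrophil antigen gene Cd177 (6.77 ± 0.44), the acute phase gene Saa3 (6.64 ± 0.79), the prostaglandin synthase Ptgs2 (6.36 ± 0.48), Atf3 (5.96 ± 0.38) and the chemokine Cxcl3 (5.96 ± 0.31). The largest falls were of Gpr155 (-3.88 ± 0.48), the membrane protein gene Pmp22 (-3.82 ± 0.24), the transporter gene Slc16a12 (-3.68 ± 0.35), the dehydrogenase gene Adh1 (-3.46 ± 0.26), the mucosal keratin Krt4 (-3.41 ± 0.28), the stem cell receptor Lgr6 (-3.31 ± 0.25), the peroxisomal thiolase Acaa1b (-3.26 ± 0.28) and the chemokine-scavenging receptor Ackr3 (-3.25 ± 0.18). Of the rises 449 reached 2-fold, and of the falls 820.

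Inflammatory genes stood above 0 h at 24 h in WT: 23 of 30 inflammatory genes rose, 1 fell and 6 did not pass, with 24 and 1 adjusted over the list alone (camera adjusted p = 1.79e-16, adjusted p = 0.00366 with an estimated correlation). Cxcl1 stood at 5.88 and Il6 at 2.04, while Il18, chosen after its values were seen, fell by 0.83. Outside the list, S100a8 rose by 0.90 and Lcn2, which binds bacterial siderophores, by 0.86. Of the NF-kB genes, 21 of 29 rose and 1 fell, the same counts as adjusted over the list alone (camera adjusted p = 5.68e-12, adjusted p = 0.000968 with an estimated correlation). Icam1 rose by 2.28, Nfkbia by 2.11, Birc3 by 1.94 and Tnfaip3 by 3.05, and Rela, chosen after its values were seen, fell by 0.44. Of 38 immediate early genes 27 rose, with 29 adjusted over the list alone (camera adjusted p = 3.43e-14, adjusted p = 0.0891 with an estimated correlation), including Fos (3.94), Ier3 (3.06) and Phlda1 (3.30). Hes1 (-1.58), Sgk1 (-1.51) and Ccn2 (-0.93), chosen after their values were seen, fell. Mucosal antimicrobial genes rose in 18 of 31 cases and fell in 2, counts that held adjusted over the list alone (camera adjusted p = 3.62e-06, adjusted p = 0.0891 with an estimated correlation). Chil1 rose by 3.56, Pglyrp1, which binds bacterial cell walls, by 2.52, Slpi by 2.34 and the immunoglobulin carrier Pigr by 1.90, and Defb1 (-1.40) and Duoxa1 (-0.36), chosen after their values were seen, fell. Leaving out WT_24h replicate 3 ended the calls of Il18 (-0.63, adjusted p = 0.132) and Duoxa1 (-0.28, 0.200). Quantile normalization ended that of Rela (-0.24, 0.173, range of adjusted p over the alternatives 0.00057 to 0.173).

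At 24 h in WT, stress lists did not all move alike. In the unfolded protein and integrated stress response, 26 of 28 genes rose and none fell, 27 adjusted over the list alone (camera adjusted p = 6.60e-20, adjusted p = 0.000109 with an estimated correlation). Chac1, a glutathione-degrading enzyme, rose by 3.48, Trib3 by 2.89, Herpud1 by 1.99 and Slc3a2 by 1.81. Hypoxia and glycolysis genes rose in 24 of 28 cases, 25 adjusted over the list alone (camera adjusted p = 1.77e-15, adjusted p = 0.0891 with an estimated correlation), led by Ero1a (5.34), Adm (4.69), Hk2 (2.84) and Vegfa (2.82). Cholesterol synthesis genes rose in 15 of 19 cases and fell in 1, also adjusted over the list alone (camera adjusted p = 2.04e-08, adjusted p = 0.0425 with an estimated correlation). Mvd rose by 2.28, Hmgcs1 by 1.69, Msmo1 by 1.55 and Cyp51 by 1.36, and Ebp, chosen after its values were seen, fell by 0.86. Heat shock genes were mixed, with 8 of 16 up and 3 down, also adjusted over the list alone (camera adjusted p = 0.00163, adjusted p = 0.225 with an estimated correlation). Hspa1a rose by 4.47, Hspa1b by 3.36, Dnajb1 by 2.91 and Hspa8 by 1.64, and Hspa4l (-0.54), Chordc1 (-0.44) and Cryab (-0.42), chosen after their values were seen, fell. Without WT_24h replicate 2 the falls of Hspa4l (-0.47, adjusted p = 0.0976) and Cryab (-0.39, 0.0723) were not called, nor was that of Chordc1 without WT_24h replicate 3 (-0.42, 0.113).

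Of 23 cytochrome P450 and other xenobiotic genes 16 fell and 1 rose in WT at 24 h, 17 and 1 adjusted over the list alone (camera adjusted p = 7.33e-08, adjusted p = 0.0346 with an estimated correlation). Adh7 fell by 2.70, Cyp4a12a by 2.31 and Cyp4b1 by 1.78, and Fmo1, chosen after its values were seen, rose by 1.24. Basal cell genes fell in 12 of 20 cases and rose in 3, also adjusted over the list alone (camera adjusted p = 0.000177, adjusted p = 0.0968 with an estimated correlation), with Dapl1 at -2.81, Krt15 at -1.92, Dst at -1.68 and Snai2 at -1.30. The basal genes that rose were Sfn (1.18), Krt17 (0.83) and Aqp3 (0.75), chosen after their values were seen. Krt17 lost its call without WT_24h replicate 3 (0.63, adjusted p = 0.0773) and Aqp3 without WT_24h replicate 2 (0.61, 0.0811). Squamous and wound genes rose in 16 of 25 cases and fell in 1, 17 and 2 adjusted over the list alone (camera adjusted p = 2.63e-07, adjusted p = 0.0891 with an estimated correlation), with Sprr2d, a cornified envelope gene, at 4.73, Hbegf at 3.89 and Plaur at 2.68. The squamous gene that fell was Krt4. Metalloproteinases and inhibitors rose in 9 of 29 cases and fell in 2, 12 and 2 adjusted over the list alone (camera adjusted p = 0.0138, adjusted p = 0.112 with an estimated correlation). The collagenase Mmp13 rose by 4.43, Adam8 by 1.36 and Adamts4 by 1.05, and Mmp11 (-2.14) and Timp2 (-0.61, chosen after its values were seen) fell.

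Of 35 cell cycle genes in WT at 24 h, 15 fell, 19 did not pass and 1, the spindle gene Tpx2, rose by 0.68, with 23 and 1 adjusted over the list alone (camera adjusted p = 0.000334, adjusted p = 0.349 with an estimated correlation). Cdk1 stood at -1.55, Cdca8 at -1.19 and the replication helicase gene Mcm6 at -1.16. Ciliated cell genes showed no common direction, with 8 of 35 up and 4 down, also adjusted over the list alone (camera adjusted p = 0.585, adjusted p = 0.867 with an estimated correlation). Dnaic2 rose by 0.63, Cfap53 by 0.72 and Spag16 by 0.56. The 4 that fell were Myb (-2.11) and, chosen after their values were seen, Tekt4 (-0.41), Dynlrb2 (-0.33) and Tppp3 (-0.29), which lost their calls without WT_24h replicate 2 (-0.23, -0.20 and -0.25, adjusted p = 0.256, 0.261 and 0.109). Of 24 leukocyte markers 7 rose, 2 fell and 15 did not pass, also adjusted over the list alone (camera adjusted p = 0.107, adjusted p = 0.654 with an estimated correlation). Cybb, of the phagocyte oxidase, rose by 3.58, Cd68 by 1.88, Lyz2 by 1.29 and Cd3e by 0.65. Csf1r (-0.57) and Coro1a (-0.41), chosen after their values were seen, fell. Without WT_24h replicate 2 the call of Csf1r ended (-0.43, 0.217), and without WT_24h replicate 3 that of Coro1a (-0.32, 0.194).

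**Figure D2:**
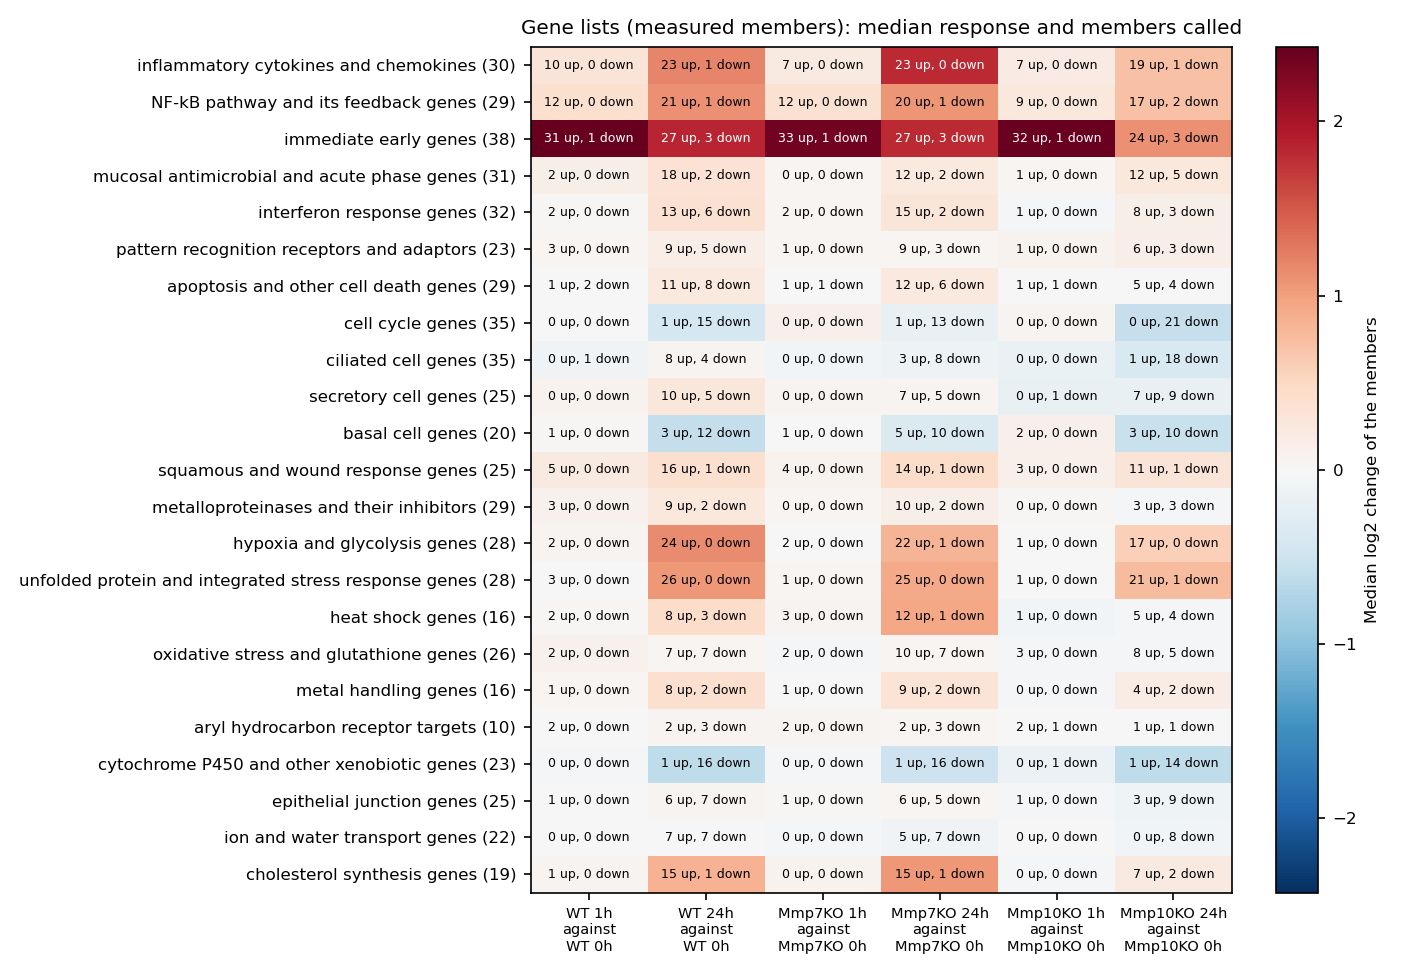
Median log2 change (colour) of the measured members of 23 gene lists (vertical, number of members in brackets) in the 6 responses (horizontal), with the members called up and down written in each cell. Immediate early genes had medians of 2.43, 2.35 and 2.39 at 1 h in WT, Mmp7KO and Mmp10KO, and xenobiotic genes medians of -0.61, -0.51 and -0.62 at 24 h.

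In Mmp7KO cells at 1 h, Cxcl2 rose 168-fold (log2 7.39 ± 0.31 SE, n = 3 and 3), with Atf3 at 6.62 ± 0.34, Fosb at 6.05 ± 0.15 and Nr4a1 at 5.98 ± 0.21. The largest falls were of Zfp866 (-1.59), H3f3b (-1.28), Zfp748 (-1.04) and Zfp551 (-0.87). Immediate early genes rose in 33 of 38 cases, 35 adjusted over the list alone (camera adjusted p = 3.37e-190, adjusted p = 8.02e-07 with an estimated correlation), including Egr1 (5.11) and the synaptic gene Arc (3.22), while Hes1, chosen after its values were seen, fell by 0.67. NF-kB genes rose in 12 of 29 cases, 16 adjusted over the list alone (camera adjusted p = 7.27e-38, adjusted p = 8.02e-07 with an estimated correlation), with Nfkbiz at 3.86, Tnfaip3 at 3.61, Nfkbia at 3.30 and Icam1 at 1.48. Leukocyte markers were higher by camera (adjusted p = 1.89e-05, adjusted p = 0.257 with an estimated correlation), though none of 24 passed limma's test, and 4 rose adjusted over the list alone. In all, 171 genes rose and 24 fell, with 386 and 256 under array weights and 197 and 71 after quantile normalization. Of the 171 genes that rose, 150 also rose in WT at 1 h, where independent calls would give 2.08, and 17 fell in both.

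At 24 h in Mmp7KO, 2028 genes rose and 3340 fell. Cxcl2 rose 340-fold (log2 8.41 ± 0.31 SE, n = 3 and 3) and Ptgs2 118-fold (6.88 ± 0.43). Cd177 (6.54), Ccl20 (6.29), Csf3 (6.25), Saa3 (6.15), Cxcl3 (6.10) and Atf3 (5.95) followed. The largest falls were of Gpr155 (-4.11), Lrrc26, a potassium channel subunit (-3.61), Id4, an inhibitor of differentiation factors (-3.18), the insulin receptor substrate Irs1 (-3.09), Pmp22 (-3.07), Ackr3 (-3.05), Adh1 (-2.96) and Prr18 (-2.94). Calls shared with the WT 24 h response numbered 1325 genes up and 2874 down, where independent calls would give 318 and 740, and 7 genes moved in opposite directions. Across all genes the 24 h responses of the 2 genotypes correlated at r = 0.905, though genes are not independent replicates.

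In Mmp7KO at 24 h, inflammatory genes rose in 23 of 30 cases, 24 adjusted over the list alone (camera adjusted p = 1.90e-21, adjusted p = 0.000973 with an estimated correlation), with Cxcl1 at 4.04, Il6 at 3.60 and Lif at 3.33. Outside the list, Fos rose by 3.87 and Lcn2 by 1.01, and S100a8 (0.31) did not pass. NF-kB genes rose in 20 of 29 cases, 21 adjusted over the list alone (camera adjusted p = 2.74e-16, adjusted p = 0.000152 with an estimated correlation), including Tnfaip3 (2.96), Nfkbia (2.26), Icam1 (2.20), Birc3 (1.74) and Tnip1 (1.44). Rela, chosen after its values were seen, fell by 0.33, a call that ended without Mmp7KO_24h replicate 1 (-0.25, adjusted p = 0.0584). Stress response genes rose in 25 of 28 cases, 26 adjusted over the list alone (camera adjusted p = 2.45e-22, adjusted p = 5.31e-05 with an estimated correlation), with Chac1 at 4.49, Trib3 at 3.42, Slc3a2 at 2.31 and Asns at 1.99. Heat shock genes rose in 12 of 16 cases, also adjusted over the list alone (camera adjusted p = 1.23e-09, adjusted p = 0.0247 with an estimated correlation), with Hspa1a at 5.26, Hspa1b at 3.73, Dnajb1 at 3.29 and Hspa8 at 1.84. Hspa4l, chosen after its values were seen, fell by 0.55.

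In Mmp7KO at 24 h, cholesterol synthesis genes rose in 15 of 19 cases, also adjusted over the list alone (camera adjusted p = 4.63e-12, adjusted p = 0.0131 with an estimated correlation), with Mvd at 2.45, Msmo1 at 1.75, Cyp51 at 1.33 and Hsd17b7 at 1.09, and Ebp, chosen after its values were seen, at -1.09. Hypoxia and glycolysis genes rose in 22 of 28 cases, also adjusted over the list alone (camera adjusted p = 4.14e-14, adjusted p = 0.0730 with an estimated correlation), with Ero1a at 5.20, Adm at 4.62, Vegfa at 3.06 and Hk2 at 3.02. Pdk1, chosen after its values were seen, fell by 0.69. Xenobiotic genes fell in 16 of 23 cases, also adjusted over the list alone (camera adjusted p = 5.39e-08, adjusted p = 0.0228 with an estimated correlation), including Adh7 (-2.25), Cyp4a12a (-1.86) and Cyp4b1 (-1.72), with Fmo1, chosen after its values were seen, at 0.80. Leukocyte markers rose in 9 of 24 cases, also adjusted over the list alone (camera adjusted p = 9.00e-05, adjusted p = 0.244 with an estimated correlation), with Cybb at 3.70, Cd68 at 2.59, Lyz2 at 1.21 and Fcgr2b at 0.47.

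Mmp10KO cells at 1 h again raised Cxcl2, 121-fold (log2 6.92 ± 0.31 SE, n = 3 and 3), Atf3 (6.51 ± 0.34), Nr4a1 (6.19 ± 0.21) and Fosb (5.66 ± 0.15). The cathepsin gene Ctss (-1.51), Ctu1, of transfer RNA modification (-1.13), Mettl18 (-1.01) and Ppp1r3b, a glycogen regulator (-0.92), fell. Immediate early genes rose in 32 of 38 cases, 33 adjusted over the list alone (camera adjusted p = 5.73e-119, adjusted p = 3.83e-05 with an estimated correlation), with Egr1 at 4.93 and Arc at 3.21, while Hes1, chosen after its values were seen, fell by 0.45. NF-kB genes rose in 9 of 29 cases, 12 adjusted over the list alone (camera adjusted p = 2.04e-19, adjusted p = 4.63e-05 with an estimated correlation), with Tnfaip3 at 3.99, Nfkbia at 3.16, Nfkbiz at 2.73 and Icam1 at 1.36. In all 161 genes rose and 48 fell, of which 135 and 17 did so in WT at 1 h. Without Mmp10KO_0h replicate 3 the falls of Ctss (-1.31, adjusted p = 0.238) and Hes1 (-0.36, 0.132) lost their calls. Ctss did so in 12 of the 25 fits, and Ctu1 (-1.04, 0.164) and Ppp1r3b (-0.86, 0.137) without Mmp10KO_0h replicate 1. The array with the highest 18S signal, Mmp10KO_1h replicate 1, belongs to this comparison.

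After 24 h, Mmp10KO cells had 1930 genes up and 3032 down. Cxcl2 rose 107-fold (log2 6.74 ± 0.34 SE, n = 3 and 2) and Cxcl1 58.8-fold (5.88 ± 0.33), followed by Csf3 (5.46), Ccl20 (5.44), Cd177 (5.07), Atf3 (5.02), the neurotrophic factor Artn (4.89) and Ptgs2 (4.84). The largest falls were of Gpr155 (-3.78), Ackr3 (-3.05), the potassium channel Kcnj13 (-2.91), the tight junction gene Cldn8 (-2.77), Cavin2 (-2.67), Pmp22 (-2.66), Lgr6 (-2.57) and Ctss (-2.42). With WT at 24 h, 910 rises and 1978 falls were shared, where independent calls would give 303 and 672, and 51 genes moved in opposite directions (r = 0.760 across genes, which are not independent replicates). Without Mmp10KO_24h replicate 3, an array with high 18S signal, the 4962 calls became 1923.

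Inflammatory genes rose in 19 of 30 cases in Mmp10KO at 24 h and fell in 1, also adjusted over the list alone (camera adjusted p = 9.39e-12, adjusted p = 0.0175 with an estimated correlation). Lif stood at 2.38, while Il6 (0.18) did not pass and Il18, chosen after its values were seen, fell by 1.38. Outside the list, Saa3 rose by 3.24, Fos by 3.03 and Lcn2 by 1.08, and S100a8 (0.19) did not pass. NF-kB genes rose in 17 of 29 cases and fell in 2, 20 and 3 adjusted over the list alone (camera adjusted p = 7.53e-11, adjusted p = 0.00159 with an estimated correlation). Tnfaip2 rose by 2.90, Nfkbia by 2.50, Icam1 by 2.04, Tnfaip3 by 1.85 and Birc3 by 1.66, and Birc2 (-0.83) and Rela (-0.48), chosen after their values were seen, fell. Stress response genes rose in 21 of 28 cases and fell in 1, also adjusted over the list alone (camera adjusted p = 4.07e-16, adjusted p = 0.000385 with an estimated correlation), with Chac1 at 4.61, the regulator Atf4 at 2.00, Asns at 1.88, Herpud1 at 1.66 and Dnajc3, chosen after its values were seen, at -0.80. Hypoxia and glycolysis genes rose in 17 of 28 cases, 21 adjusted over the list alone (camera adjusted p = 1.82e-09, adjusted p = 0.260 with an estimated correlation), with Ero1a at 4.23, Adm at 3.47, Hk2 at 2.65 and the glucose transporter Slc2a1 at 2.56. Without Mmp10KO_24h replicate 3, Birc2 (-0.32, adjusted p = 0.274) and Dnajc3 (-0.17, 0.692) lost their calls. A fit of the compared groups alone ended those of Lcn2 (adjusted p = 0.0596, range over the alternatives 3.70e-05 to 0.0596) and Saa3 (range 0.000101 to 0.171).

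Ciliated cell genes fell in 18 of 35 cases in Mmp10KO at 24 h and rose in 1, 19 and 1 adjusted over the list alone (camera adjusted p = 3.57e-05, adjusted p = 0.347 with an estimated correlation), among them Myb (-2.22), Tekt4 (-0.75), Meig1 (-0.72) and Tppp3 (-0.57), with Cdhr3, chosen after its values were seen, at 0.39. Cell cycle genes fell in 21 of 35 cases, 23 adjusted over the list alone (camera adjusted p = 1.31e-07, adjusted p = 0.260 with an estimated correlation), with Ube2c at -2.02, Cdk1 at -1.58, Cdc20 at -1.27 and Mcm6 at -1.20. Xenobiotic genes fell in 14 of 23 cases, 17 adjusted over the list alone (camera adjusted p = 6.51e-09, adjusted p = 0.0204 with an estimated correlation), including Adh7 (-1.95), Cyp4a12a (-1.78), Cyp4b1 (-1.58) and Fmo2 (-0.93). Fmo2 turned to 0.54 (adjusted p = 0.0151, range over the alternatives 1.44e-07 to 0.0151) when the probe set with the largest spread stood for it, and Fmo1, chosen after its values were seen, rose by 0.37. Cholesterol synthesis genes rose in 7 of 19 cases and fell in 2, also adjusted over the list alone (camera adjusted p = 0.0238, adjusted p = 0.367 with an estimated correlation), with Mvd at 1.79, Insig1 at 1.49 and Msmo1 at 0.80. The 2 that fell were Ebp (-1.06) and Tm7sf2 (-0.69), which was chosen after its values were seen. Leukocyte markers rose in 4 of 24 cases and fell in 4, 8 and 4 adjusted over the list alone (camera adjusted p = 0.184, adjusted p = 0.670 with an estimated correlation). Cybb (2.99), Cd68 (2.10) and, chosen after their values were seen, Lyz2 (0.76) and Itgam (0.44) rose, and Cd52 (-1.50), Tyrobp (-1.08), Adgre1 (-0.92) and Csf1r (-0.63) fell, Tyrobp and Csf1r being chosen after their values were seen. The cholesterol call ended without Mmp10KO_0h replicate 3 (adjusted p = 0.0939), those of Cdhr3 (0.34, 0.266), Itgam (0.30, 0.313) and Csf1r (-0.49, 0.259) without Mmp10KO_24h replicate 3, and those of Fmo1 (0.22, 0.306) and Tyrobp (-0.96, 0.1004) without Mmp10KO_24h replicate 1.

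**Figure D3:**
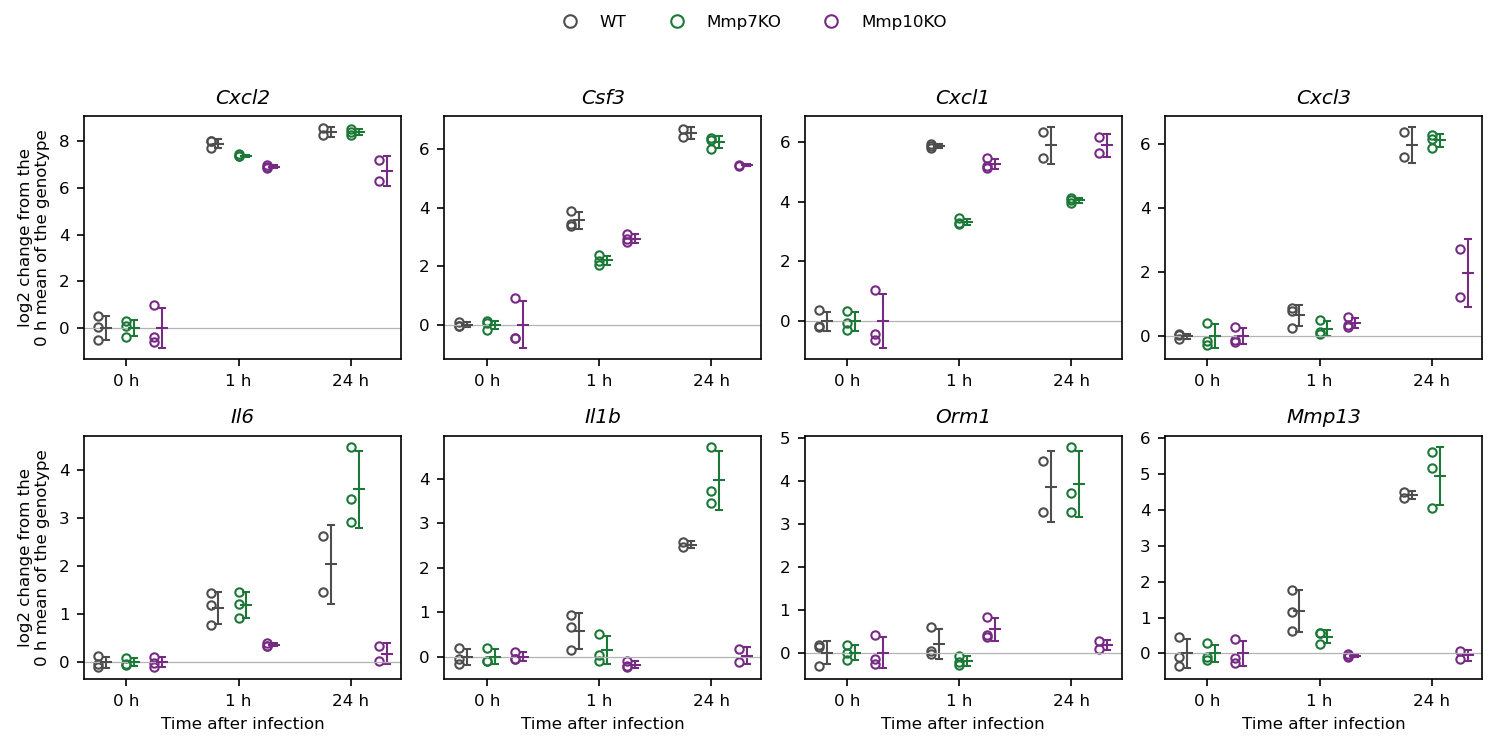
Log2 change of 8 genes from the 0 h mean of their genotype (y axis) at 0, 1 and 24 h (x axis). Each circle is an array and bars give the mean ± SD. At 24 h Mmp13 averaged 4.43 in WT, 4.96 in Mmp7KO and -0.06 in Mmp10KO, and Cxcl2 8.40, 8.41 and 6.74.

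The response of Mmp7KO was then set against that of WT. At 1 h limma called no difference (0 of 18193 genes, 736 at an unadjusted p under 0.05). Cxcl1 had the lowest adjusted p among inflammatory genes, with a response in Mmp7KO that differed from that of WT by -2.54 ± 0.42 (n = 3 in each of the 4 groups, adjusted p = 0.114). None of the 30 inflammatory genes passed, 2 were lower adjusted over the list alone, and the list had a median of -0.22 (camera adjusted p = 0.00094, adjusted p = 0.577 with an estimated correlation). Csf3 stood at -1.37, Cxcl5 at -1.62, Ccl20 at -1.10, Cxcl2 at -0.52, Il23a at -0.42 and Il6 at 0.07. Outside the list, Saa3 stood at -1.92, Lcn2 at -0.18, S100a8 at -0.09, Tnfaip3 at -0.68, Nfkbia at 0.54, Fos at 0.21 and Atf3 at -0.01. Without Mmp10KO_0h replicates 2 or 3 the count of called genes became 2 and 1.

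At 24 h the response of Mmp7KO differed from that of WT for 19 genes, 16 higher and 3 lower. After quantile normalization 1 gene was called, lower and not among the 19. The macrophage chemokine Ccl3 rose more in Mmp7KO (difference 2.62 ± 0.46, n = 3, 3, 3 and 2, adjusted p = 0.0245). Other higher genes were Dapl1 (1.51), the ubiquitin ligase Rnf183 (1.37), Osgin1, an oxidative stress gene (1.34), Gclc, of glutathione synthesis (0.91), and the small heat shock protein Cryab (0.87). The lower genes were the transcription cofactor Cited1 (-1.90 ± 0.30, adjusted p = 0.0177), the chloride channel Clcn1 (-0.83) and 2610528A11Rik (-2.98), chosen after its values were seen. Each of these 9 calls ended without WT_24h replicate 3, Ccl3 falling to 2.23 (adjusted p = 0.163), Cited1 to -1.41 (0.104) and Gclc to 0.71 (0.104). The count was 0 without WT_24h replicate 3 or WT_0h replicate 1, 8 without WT_0h replicate 2, 6 without WT_0h replicate 3, 3, 7 and 9 without Mmp7KO_0h replicates 1, 2 and 3, and 12 without Mmp7KO_1h replicate 1, Mmp10KO_0h replicate 1 or Mmp10KO_1h replicate 2. It was 30 without WT_1h replicate 3, 40 without Mmp10KO_1h replicate 1, 43 without either Mmp10KO_24h array and 177 without WT_24h replicate 2.

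Among the lists, 1 of 20 basal cell genes, Dapl1, was higher in the Mmp7KO 24 h response than in WT, with 6 adjusted over the list alone (camera adjusted p = 7.14e-08, adjusted p = 0.0906 with an estimated correlation). The keratins Krt5 (1.12) and Krt15 (0.81) and the collagen gene Col17a1 (1.21) did not pass. Of 16 heat shock genes Cryab passed, with 6 adjusted over the list alone (camera adjusted p = 5.32e-07, adjusted p = 0.149 with an estimated correlation), and Hspb1 (1.11), Hspe1 (0.67) and Bag3 (0.63) did not. Of 26 oxidative stress genes Gclc and Osgin1 passed, with 8 adjusted over the list alone (camera adjusted p = 0.00603, adjusted p = 0.149 with an estimated correlation), and Srxn1 (0.81) and Cbr3 (0.64) did not. None of 24 leukocyte markers passed limma's test, with 5 adjusted over the list alone (camera adjusted p = 0.0160, adjusted p = 0.639 with an estimated correlation), and Fcer1g stood at 1.22, Mpeg1 at 0.93, Coro1a at 0.76 and Cd68 at 0.71. The leukocyte call ended without WT_0h replicate 3 (adjusted p = 0.092), Mmp7KO_0h replicate 1 (0.107) or Mmp7KO_24h replicate 1 (0.0732). Cryab, Clcn1 and Osgin1 lost their calls in 16, 16 and 18 of the 25 fits that left out 1 array. Without WT_24h replicate 3 they stood at 0.91, -0.67 and 0.89.

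For Mmp10KO against WT, the 1 h response differed in 6 genes. Lower in Mmp10KO were the transcription factor Egr2 (-1.99 ± 0.26, n = 3 in each of the 4 groups, adjusted p = 0.00204), the small GTPase Gem (-1.91 ± 0.25, 0.00204), Nfkbid, a nuclear NF-kB regulator (-1.84 ± 0.25, 0.00272), the kinase Map3k8 (-1.19 ± 0.19, 0.0215) and Ier5 (-0.85, 0.0384), chosen after its values were seen. Zfp551, which fell in WT, was higher (0.98 ± 0.17, 0.0384). The calls of Egr2, Gem and Nfkbid ended in a fit of the compared groups alone (adjusted p = 0.342, 0.0816 and 0.0816, with ranges over the alternatives from 1.70e-05, 1.92e-06 and 0.000197). Zfp551 (0.90, 0.215) and Map3k8 (-1.11, 0.112) lost theirs without WT_0h replicate 2 and Ier5 (-0.81, 0.176) without Mmp10KO_0h replicate 1. Zfp551 and Ier5 did so in 16 of the 25 fits each and Map3k8 in 6.

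At the level of lists, the 1 h difference of Mmp10KO from WT was lower for 2 of 29 NF-kB genes, Nfkbid and Map3k8, also adjusted over the list alone (camera adjusted p = 6.80e-05, adjusted p = 0.116 with an estimated correlation), while Nfkbiz (-0.79) and Icam1 (-0.37) did not pass. None of 25 secretory cell genes passed limma's test, with 2 adjusted over the list alone (camera adjusted p = 3.55e-08, adjusted p = 0.175 with an estimated correlation). Retnla stood at -0.97, the secretoglobin Scgb3a1 at -0.87, Bpifb1 at -1.56 and Fcgbp at -0.46. None of 24 leukocyte markers passed either, with 3 adjusted over the list alone (camera adjusted p = 2.73e-05, adjusted p = 0.365 with an estimated correlation), with Cd52 at -1.69, Tyrobp at -1.34, Adgre1 at -0.89 and Csf1r at -0.65. These lists moved in a comparison that includes Mmp10KO_1h replicate 1, whose 18S signal was 3.81. Between Mmp10KO and Mmp7KO the 1 h responses differed for 1 gene, Gem (-1.99 ± 0.25, adjusted p = 0.00184). That count was 2 without any 1 of WT_1h replicates 2 and 3, WT_24h replicates 2 and 3, Mmp7KO_0h replicate 1, Mmp7KO_1h replicates 2 and 3 and Mmp10KO_1h replicate 1, 4 without Mmp10KO_1h replicate 3, and 5 without Mmp7KO_0h replicate 3 or Mmp10KO_0h replicate 2.

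At 24 h the Mmp10KO response differed from that of WT in 1142 genes, 646 higher and 496 lower. This balance depended on the setting: 675 were higher and 806 lower without Mmp10KO_24h replicate 1, 998 and 1001 without Mmp10KO_1h replicate 1, 188 and 194 after quantile normalization, 168 and 188 with array weights, 436 and 461 in the compared groups alone, and 1117 and 563 without Mmp10KO_24h replicate 3. The collagenase Mmp13, up 21.5-fold in WT, stood at -0.06 in Mmp10KO (difference -4.48 ± 0.48 SE, n = 3, 2, 3 and 2, adjusted p = 5.08e-05). The chemokine Cxcl3 (-3.99 ± 0.44, 5.08e-05) and the acute phase genes Orm1 (-3.70 ± 0.48, 0.000232) and Lrg1 (-3.43 ± 0.52, 0.00075) also had smaller responses. Il1b (-2.50 ± 0.37), the lymphocyte chemokine Ccl5 (-1.92 ± 0.26), Il6 (-1.86 ± 0.45) and Cxcl2 (-1.67 ± 0.49, adjusted p = 0.0447) were lower too. Higher in Mmp10KO were Padi2, a protein citrullinase (2.31 ± 0.29), Pkhd1, of cilia (2.18 ± 0.24), Krt4 (1.98 ± 0.40) and Ahnak2 (1.92 ± 0.17). Cxcl2 lost its call in 17 of the 25 fits that left out 1 array (-1.22, adjusted p = 0.157 without Mmp10KO_24h replicate 1), and Il6 lost its call without WT_24h replicate 2 (-1.28, 0.102). The count was 579 without WT_24h replicate 3, 651 without WT_0h replicate 2, 727 without Mmp10KO_0h replicate 2, 739 without WT_0h replicate 3 and 1999 without Mmp10KO_1h replicate 1.

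Over the 6887 genes called in WT at 24 h, the slope of a genotype's response on that of WT was 0.878 in Mmp7KO and 0.606 in Mmp10KO, and 94.5% and 88.0% of the genes moved the WT way. By array, the Mmp7KO slopes were 0.831 to 0.907, and those of Mmp10KO 0.479 in replicate 1 and 0.733 in replicate 3. In replicate 1 the 3 prime minus 5 prime control signal was 0.55 for Gapdh and 0.68 for actin, against -0.35 and -0.12 in replicate 3. These signals are relative to the mean of their genotype, so they compare arrays only within a genotype. Arrays of other times reached as high, such as 0.56 for Gapdh in Mmp10KO_1h replicate 1 and 1.13 and 0.91 for Gapdh and actin in Mmp7KO_1h replicate 3. Both Mmp10KO 24 h arrays had an array weight of 0.27, and both WT 24 h arrays 0.63. In a group of 2 the weights are equal by construction, so they show how far the pair differs and not which array is at fault. Choosing genes by WT favours WT, but over the 4962 genes called in Mmp10KO the slopes on Mmp10KO were 0.949 in WT and 0.927 in Mmp7KO.

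**Figure D4:**
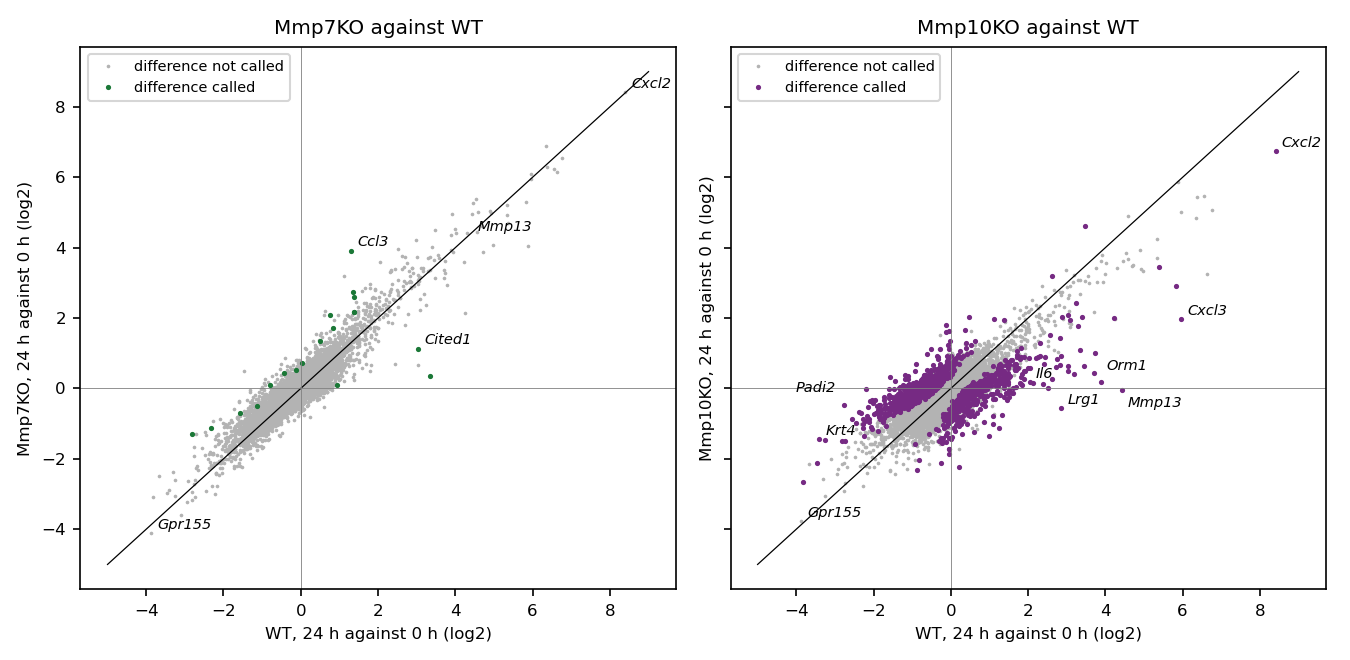
Log2 response at 24 h in Mmp7KO (left, y axis) and Mmp10KO (right, y axis) against that in WT (x axis). Each point is a gene, coloured where the difference passed an adjusted p of 0.05, and the line marks equal responses. Coloured genes number 19 on the left and 1142 on the right, where Mmp13 lies at 4.43 in WT and -0.06 in Mmp10KO.

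Inflammatory genes carried part of this 24 h difference of Mmp10KO from WT: 7 of 30 were lower and 0 higher, 9 adjusted over the list alone, with a median of -0.48 (camera adjusted p = 1.89e-06, adjusted p = 0.225 with an estimated correlation). Csf3 (-1.09) and Ccl20 (-0.93) did not pass, nor, outside the list, did Saa3 (-3.40), Tnfaip3 (-1.20), Atf3 (-0.95), Fos (-0.91), S100a8 (-0.72), Nfkbia (0.39) and Lcn2 (0.22), and the Cxcl1 responses differed by less than 0.01 ± 0.47. Mucosal antimicrobial genes were lower in 4 of 31 cases, 6 adjusted over the list alone (camera adjusted p = 0.00304, adjusted p = 0.302 with an estimated correlation): Cfb (-2.92), the bactericidal-type protein gene Bpifb1 (-2.43), Pigr (-1.02) and the lectin Reg3g (-0.61). Metalloproteinases and inhibitors were lower in 4 of 29 cases and higher in 1, also adjusted over the list alone (camera adjusted p = 0.0251, adjusted p = 0.264 with an estimated correlation). Beside Mmp13, Timp1 (-1.73), Adam10 (-1.14, chosen after its values were seen) and Adamts4 (-0.87) were lower and Mmp11 (1.61) higher. Of 24 leukocyte markers Adgre1 alone was lower (-1.19), also adjusted over the list alone (camera adjusted p = 0.511, adjusted p = 0.879 with an estimated correlation), and Cd52 (-1.14), Fcgr2b (-0.38) and Coro1a (0.43) did not pass. Cfb lost its call in 17 of the 25 fits (-2.91 without WT_24h replicate 3). Other calls ended without WT_24h replicate 3 for Pigr (-0.998) and Adam10 (-1.02) and without replicate 2 for Timp1 (-1.47). Without Mmp10KO_24h replicate 3 Bpifb1 (-2.04) and Reg3g (-0.45) lost theirs, and the metalloproteinase list without replicate 1.

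Metabolic and ciliated genes were also among those lower. Cholesterol synthesis genes responded less in Mmp10KO than in WT at 24 h in 6 of 19 cases, 11 adjusted over the list alone (camera adjusted p = 1.18e-08, adjusted p = 0.140 with an estimated correlation), with Idi1 at -1.60, Stard4 at -1.57, Hmgcs1 at -1.16 and Cyp51 at -1.15. Hypoxia and glycolysis genes were lower in 6 of 28 cases, 12 adjusted over the list alone (camera adjusted p = 6.75e-08, adjusted p = 0.290 with an estimated correlation), with Vegfa at -1.40, Hif1a at -1.05, Car9 at -0.94 and Tpi1 at -0.77. Ciliated cell genes were lower in 5 of 35 cases, 15 adjusted over the list alone (camera adjusted p = 7.79e-08, adjusted p = 0.264 with an estimated correlation): Lrrc6 (-1.19), the dynein genes Dnaic2 (-0.99) and Dnaic1 (-0.97), Ccdc39 (-0.72) and Cfap53 (-0.67, chosen after its values were seen). The hypoxia call ended without Mmp10KO_24h replicate 1 (adjusted p = 0.0509). Leaving out WT_24h replicate 3 ended those of Tpi1 (-0.48, adjusted p = 0.129), Car9 (-0.51, 0.207), Lrrc6 (-0.97, 0.114), Dnaic1 (-0.76, 0.132), Ccdc39 (-0.74, 0.0851) and Cfap53 (-0.53, 0.181).

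The knockouts' 24 h responses differed from each other in 968 genes, 342 higher in Mmp10KO and 626 lower. The higher ones were more numerous without Mmp10KO_24h replicate 3 (714 and 596), without both arrays of high 18S (1181 and 1069) and with the 18S covariate (475 and 447). Mmp13 (-5.01 ± 0.46 SE, n = 3, 2, 3 and 3), Cxcl3 (-4.12), Il1b (-3.95) and the macrophage elastase Mmp12 (-3.94) had smaller responses in Mmp10KO. Cxcl1 (1.84 ± 0.45, adjusted p = 0.0189), Sertad4 (1.75), Padi1 (1.71) and Agbl5 (1.71) had larger ones. Of the 1142 genes that differed between Mmp10KO and WT, 204 were also higher and 278 also lower here, but the same Mmp10KO arrays serve both comparisons. Heat shock genes were lower in 10 of 16 cases, 15 adjusted over the list alone (camera adjusted p = 1.24e-14, adjusted p = 0.0172 with an estimated correlation), with Dnaja1 at -1.36, Bag3 at -1.31, Hspa8 at -1.18 and Hspe1 at -1.15. Cholesterol synthesis genes were lower in 8 of 19 cases, 13 adjusted over the list alone (camera adjusted p = 8.13e-13, adjusted p = 0.0172 with an estimated correlation), with Stard4 at -1.81, Cyp51 at -1.12, Sqle at -0.93 and Hsd17b7 at -0.75. Single arrays moved the count to 596 and 628 (without Mmp7KO_0h replicates 2 and 1), 599 (Mmp7KO_24h replicate 1), 613 and 635 (Mmp10KO_0h replicates 1 and 2), 1824 (Mmp10KO_1h replicate 1) and 1862 (Mmp10KO_24h replicate 1). Sertad4 lost its call in 12 of the 25 fits (0.91 without Mmp10KO_24h replicate 1) and Cxcl1 without Mmp10KO_24h replicate 3 (1.57).

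Inflammatory genes responded less in Mmp10KO than in Mmp7KO at 24 h in 11 of 30 cases and more in 1, Cxcl1, 12 and 1 adjusted over the list alone (camera adjusted p = 3.45e-09, adjusted p = 0.0457 with an estimated correlation). Il6 stood at -3.42, Ccl5 at -1.92 and Cxcl2 at -1.67, and Ccl20 (-0.85) and Csf3 (-0.79) did not pass. Outside the list, Saa3 (-2.91), Tnfaip3 (-1.11), Atf3 (-0.93), Fos (-0.84), S100a8 (-0.12), Nfkbia (0.24) and Lcn2 (0.06) did not pass either. Metalloproteinases and inhibitors were lower in 7 of 29 cases and higher in 1, 8 and 1 adjusted over the list alone (camera adjusted p = 0.00358, adjusted p = 0.0752 with an estimated correlation), with Timp1 at -1.92, Mmp23 at -1.11 and Mmp11, chosen after its values were seen, at 0.80. Of 24 leukocyte markers Cd52 (-2.13), Adgre1 (-1.30) and Mpeg1 (-1.24) were lower, 5 adjusted over the list alone (camera adjusted p = 0.00405, adjusted p = 0.445 with an estimated correlation), and Tyrobp (-1.50) did not pass. Calls ended without Mmp10KO_24h replicate 1 for Cxcl2 (-1.22, adjusted p = 0.127) and for the metalloproteinase (adjusted p = 0.0586) and leukocyte lists (0.275), without Mmp10KO_24h replicate 3 for Mmp23 (-0.78, 0.0976) and Mmp11 (0.60, 0.1504), and without Mmp7KO_24h replicate 1 for Mpeg1 (-1.10, 0.0694).

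The targeted genes could be read only as changes within a genotype. Mmp7 rose by 24 h in WT (0.73 ± 0.20, n = 3 and 2, adjusted p = 0.00706) and in Mmp10KO (0.91 ± 0.20, n = 3 and 2, adjusted p = 0.00215). In Mmp7KO it stood at 0.38 (adjusted p = 0.133), and the difference of that response from WT did not pass (-0.35). The Mmp10KO rise lost its call without Mmp10KO_24h replicate 3 (0.63, adjusted p = 0.0993). At 1 h Mmp7 stood at 0.23, -0.24 and -0.01 in WT, Mmp7KO and Mmp10KO. Mmp10 did not pass in any response, at 0.10, 0.05 and 0.38 at 1 h and 0.25, 0.07 and -0.08 at 24 h in the same order. Differences between responses did not pass for either gene, running from -0.47 to 0.54 for Mmp7 and from -0.33 to 0.33 for Mmp10.

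Mmp7 and Mmp10 lie in a metalloproteinase cluster on chromosome 9. In the 24 h difference of Mmp10KO from WT, 4 of 37 neighbours were called (Mmp13 and, at -1.18, -0.83 and -0.45, Tmem123, Casp4 and Cep126) against 1138 of 18156 other genes (two-sided Fisher's exact test p = 0.291). In that of Mmp10KO from Mmp7KO, 4 of 37 were called (Mmp12, Mmp13, Aasdhppt at -1.04 and Casp4 at -0.94) against 964 of 18156 (exact p = 0.132). The other 4 differences called none of the 37, where limma called at most 19 of the other genes (exact p = 1 in each). Tmem123 lost its call without WT_24h replicate 3 (-1.11) and Aasdhppt without Mmp10KO_24h replicate 3 (-0.79). Cep126 lost its call in 17 of the 25 fits that left out 1 array.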

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

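The tests of the 3 patterns that are weighed were chosen after the results were seen, while the splits of the samples were planned before. Differences between genotypes were taken up here because the test of the difference itself passed, 18S signals because they lay above those of all uninfected arrays of their genotype, and probe sets without a single gene because no comparison used them.

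At 24 h, 1142 genes responded differently in Mmp10KO and WT, with slopes on the WT response of 0.479 and 0.733 in the Mmp10KO arrays. Poor RNA that follows the 18S signal is argued against as the whole cause only as far as a linear covariate can tell. With that covariate the median size of the difference over these genes went from 0.77 to 0.73 and its SE from 0.185 to 0.190. Of these genes 819 stayed called, among 1670 called in all. The bar, that most stay called, was set after the results were seen. The widest spread of the signal within a group was in Mmp10KO at 1 h (3.81, -2.18 and -1.75), so the covariate rests largely on replicate 1 there. In Mmp10KO the signal also differed with time, at -1.11 to -0.88 at 0 h and 0.18 and 2.81 at 24 h. The length of the labelled RNA, read from the 3 prime and 5 prime control signals, cannot be told apart from an effect: with that covariate the size went to 0.66 and its SE to 0.204, which ended most calls and left 235, while all 1142 genes kept their direction. Replicate 1, with the smaller slope, also stood apart from replicate 3 in these signals, which can be compared only within a genotype because of the centring. A single weak array cannot be told apart from an effect for most of the genes: 730 stayed called without Mmp10KO_24h replicate 1 and 828 without replicate 3, but each fit rests on the other array alone, and 478 stayed called in both. A fault of both arrays was not tested. A difference in processing between the genotypes, whose values were centred apart, was not tested either. A biological effect of losing Mmp10 stays open.

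Mmp13 rose by 4.43 and 4.96 at 24 h in WT and Mmp7KO and stood at -0.06 in Mmp10KO, and 12 of 125 genes that rose by at least 2 log2 units in both other genotypes had under 0.25 of the WT rise in Mmp10KO, where the same count gave 0 of 76 for WT and 0 of 72 for Mmp7KO. A change near the deleted gene stays open for the genes on chromosome 9, where Fisher's exact test gave p = 0.291 (odds ratio 1.81, 95% interval 0.466 to 5.11) and camera found the neighbours lower (adjusted p = 0.0162, adjusted p = 0.264 with an estimated correlation). The other 11 such genes lie outside chromosome 9, and no test addressed an indirect effect of changed neighbours on them. Among them are Il6 (2.04, 3.60 and 0.18 in WT, Mmp7KO and Mmp10KO), Il1b (2.52, 3.97 and 0.02) and Cxcr4 (3.70, 3.36 and 0.45), and they are consistent with a smaller response of many genes. These genes were found and tested on the same data, so this is a hypothesis.

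In WT, 181 genes fell at 1 h, several of them zinc finger genes. The array WT_1h replicate 3 (median -0.77 over these genes, against -0.43 and -0.49 in the others) is argued against as the whole cause, because the same genes had medians of -0.26 in Mmp10KO and -0.23 in Mmp7KO. Zinc finger genes can cover only part of the falls: of 336 named Zfp, 45 fell in WT, 9 in Mmp7KO and 10 in Mmp10KO. The medians of the 336 were -0.16, -0.06 and -0.08, with a one-sided permutation p of 1e-05 in both knockouts, the smallest 100000 draws give. Genes are not independent replicates. The name was picked after members had been seen to fall.

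Exchanging arrays between groups gave these counts. For 1 h against 0 h in WT the real split called 402 genes and the highest other 0, in Mmp7KO 195 and 0, and in Mmp10KO 209 and 27, and for 24 h in Mmp7KO 5368 and 0. In each of these, 1 of 10 splits reached the real count, and 10 splits are too few for a share under 0.05. For the 1 h difference of Mmp7KO from WT, where the real split called 0 genes, 100 of 100 splits did as well and the highest other called 1, which carries no information because any split reaches 0. For that of Mmp10KO from WT, 2 of 100 splits reached the real 6, the real split being 1 of them. The other called 85, and the reason was not tested. For Mmp10KO against Mmp7KO at 1 h, 1 of 100 splits reached the real 1 and the highest other called 0.

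Beside the 6 genes of the 1 h difference of Mmp10KO from WT, Egr2 (-1.99), Gem (-1.91), Nfkbid (-1.84), Map3k8 (-1.19), Ier5 (-0.85) and Zfp551 (0.98), the NF-kB, leukocyte and secretory lists were lower by camera (adjusted p = 6.80e-05, 2.73e-05 and 3.55e-08). None of the 3 held with an estimated correlation (adjusted p = 0.116, 0.365 and 0.175). The inflammatory (0.000633), mucosal (0.00858), heat shock, oxidative stress and cholesterol lists (0.0331 each) were lower by camera too, and none held with an estimated correlation (0.365 or above). The 1 h difference between the knockouts was 1 gene, Gem (-1.99), with the secretory (2.52e-07), leukocyte (1.35e-05), cholesterol (0.000337), NF-kB, interferon and cell cycle lists (0.0266 each) lower by camera and none held with an estimated correlation (0.328 or above). That of Mmp7KO from WT was none, with the inflammatory list lower by camera (adjusted p = 0.00094, adjusted p = 0.577 with an estimated correlation), the mucosal list lower (0.00225 and 0.577) and cell cycle genes higher (0.00175 and 0.787).

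The 24 h difference of Mmp7KO from WT had 19 genes, among them Ccl3 (2.62), Dapl1 (1.51), Rnf183 (1.37), Osgin1 (1.34), Gclc (0.91), Cryab (0.87), Clcn1 (-0.83), Cited1 (-1.90) and 2610528A11Rik (-2.98). Of the lists, basal, heat shock, leukocyte and oxidative stress were higher by camera (adjusted p = 7.14e-08, 5.32e-07, 0.0160 and 0.00603). None of the 4 held with an estimated correlation (adjusted p = 0.0906, 0.149, 0.639 and 0.149), and the leukocyte call also ended without WT_0h replicate 3 (adjusted p = 0.092), Mmp7KO_0h replicate 1 (0.107) or Mmp7KO_24h replicate 1 (0.0732). Camera also found cell death genes higher (0.0377) and the ciliated (0.000559), hypoxia (0.0133), secretory and alveolar, neuroendocrine, ionocyte and tuft lists (0.0485 each) lower, none of which held with an estimated correlation (0.367 or above).

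Named genes of the 24 h difference of Mmp10KO from WT were higher for Padi2 (2.31), Pkhd1 (2.18), Krt4 (1.98), Ahnak2 (1.92) and Mmp11 (1.61). Lower were Mmp13 (-4.48), Cxcl3 (-3.99), Orm1 (-3.70), Lrg1 (-3.43), Cfb (-2.92), Il1b (-2.50), Bpifb1 (-2.43), Ccl5 (-1.92), Il6 (-1.86), Timp1 (-1.73), Cxcl2 (-1.67), Idi1 (-1.60), Stard4 (-1.57), Vegfa (-1.40), Lrrc6 (-1.19), Adgre1 (-1.19), Tmem123 (-1.18), Hmgcs1 (-1.16), Cyp51 (-1.15), Adam10 (-1.14), Hif1a (-1.05), Pigr (-1.02), Dnaic2 (-0.99), Dnaic1 (-0.97), Car9 (-0.94), Adamts4 (-0.87), Casp4 (-0.83), Tpi1 (-0.77), Ccdc39 (-0.72), Cfap53 (-0.67), Reg3g (-0.61) and Cep126 (-0.45). Lists lower by camera were cholesterol (adjusted p = 1.18e-08), ciliated (7.79e-08), hypoxia (6.75e-08), inflammatory (1.89e-06), metalloproteinase (0.0251) and mucosal (0.00304). None of the 6 held with an estimated correlation (adjusted p = 0.140, 0.264, 0.290, 0.225, 0.264 and 0.302). Also lower were the heat shock (9.83e-05), unfolded protein (0.00243), squamous (0.0148), secretory (0.0150), NF-kB and immediate early lists (0.0222 each), and basal genes were higher (0.0222), again none with an estimated correlation (0.225 or above).

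Between the knockouts, 968 genes differed at 24 h. Higher in Mmp10KO were Cxcl1 (1.84), Sertad4 (1.75), Padi1 (1.71), Agbl5 (1.71) and Mmp11 (0.80), and lower were Mmp13 (-5.01), Cxcl3 (-4.12), Il1b (-3.95), Mmp12 (-3.94), Il6 (-3.42), Cd52 (-2.13), Ccl5 (-1.92), Timp1 (-1.92), Stard4 (-1.81), Cxcl2 (-1.67), Dnaja1 (-1.36), Bag3 (-1.31), Adgre1 (-1.30), Mpeg1 (-1.24), Hspa8 (-1.18), Hspe1 (-1.15), Cyp51 (-1.12), Mmp23 (-1.11), Aasdhppt (-1.04), Casp4 (-0.94), Sqle (-0.93) and Hsd17b7 (-0.75). Lists lower by camera were cholesterol (adjusted p = 8.13e-13), heat shock (1.24e-14), inflammatory (3.45e-09), metalloproteinase (0.00358) and leukocyte (0.00405). With an estimated correlation the first 3 held (adjusted p = 0.0172, 0.0172 and 0.0457) and the metalloproteinase (0.0752) and leukocyte (0.445) calls ended. Also lower were the NF-kB, hypoxia and unfolded protein lists (0.000934 each), chromosome 9 neighbours (0.00172), immediate early, cell death and ciliated (0.00242 each), squamous (0.00297), cell cycle, metal and mucosal (0.00408 each), oxidative stress (0.0146) and interferon (0.0222), none with an estimated correlation (0.0752 or above).

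The 18S signal was 3.81 in Mmp10KO_1h replicate 1, and 0.18 and 2.81 in Mmp10KO_24h replicates 1 and 3. Of 10092 probe sets without a single gene, 56 rose in WT at 1 h and 1359 at 24 h, 49 and 532 in Mmp7KO, and 23 and 885 in Mmp10KO, while 52 and 578 fell in WT, 1 and 442 in Mmp7KO, and 4 and 362 in Mmp10KO.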

How the results depend on the processing

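The tests with a covariate, a robust prior, the largest-spread probe set or both high-18S arrays left out were chosen after the results were seen. Of 480 gene results, 388 were called and 289 of these were called in every setting, and of 68 list results 63 were called and 28 held in every setting, 35 losing the call with an estimated correlation. Quantile normalization ended 50 gene calls, the 3 prime and 5 prime covariate 46, the compared groups alone 39 and array weights 35. Because the values were centred, quantile normalization made unequal spreads alike. The interquartile range over genes was 0.32 and 0.38 in the WT 24 h arrays, against 0.16 to 0.19 in Mmp7KO at 1 h. Calls that this setting ended or added can therefore reflect the evened spread, and it cannot tell that apart from a fragile result. No gene result changed direction under any setting run for genes while called, except Fmo2 in Mmp10KO at 24 h, which turned to 0.54 with the largest-spread probe set. The signal over background is unknown, since levels are not in the values, so a filter on dim genes, an intensity trend and the highest-mean probe set were not run. Counts of called genes that moved by over 1.5 times follow, and the cause was not tested unless stated.

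With the largest-spread probe set, the 1 h difference of Mmp7KO from WT called 1 gene, the 24 h difference 32, and the 1 h difference between the knockouts 2. Quantile normalization called 634 genes in WT and 426 in Mmp10KO at 1 h, 1 in each difference of Mmp7KO from WT, and 382 in the 24 h difference of Mmp10KO from WT. Array weights called 784, 642 and 420 at 1 h in WT, Mmp7KO and Mmp10KO, 2429 at 24 h in Mmp10KO, 2 and 123 in the 1 h and 24 h differences of Mmp7KO from WT, 15 and 356 in those of Mmp10KO from WT, and 24 and 513 between the knockouts. The replicate number as a block called 8 in the 24 h difference of Mmp7KO from WT, and 370 and 6503 at 1 h and 24 h in WT, 181 and 5272 in Mmp7KO, 198 and 4608 in Mmp10KO, 885 in the 24 h difference of Mmp10KO from WT and 811 between the knockouts. Residuals of arrays with the same number correlated at a mean r of 0.00726 over 92 pairs, against -0.00252 over 185 other pairs.

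A minimum of 1.5-fold, stricter by construction, called 252 at 1 h in WT and 3226, 2665 and 2332 at 24 h in WT, Mmp7KO and Mmp10KO. The 18S covariate called 879 at 1 h in WT, 3016 at 24 h in Mmp10KO, 75 in the 24 h difference of Mmp7KO from WT and 2 in the 1 h difference between the knockouts. The 3 prime and 5 prime covariate called 228 at 1 h in WT, 3 and 266 in the differences of Mmp10KO from WT, and 3 and 463 between the knockouts. Without both arrays of high 18S, counts were 715 at 1 h in WT, 3024 at 24 h in Mmp10KO, 148 in the 24 h difference of Mmp7KO from WT, 2643 in that of Mmp10KO, and 5 and 2250 between the knockouts. The compared groups alone, a fit with fewer arrays, called 297 and 93 at 1 h in Mmp7KO and Mmp10KO, 2102 at 24 h in Mmp10KO, 1 and 79 in the differences of Mmp7KO from WT and 0 in the 1 h difference of Mmp10KO from WT. Each probe set on its own, more units by construction, called 790 and 13518 in WT, 319 and 10090 in Mmp7KO, 9278 at 24 h in Mmp10KO, 1 and 41 in the differences of Mmp7KO from WT, 10 and 1969 in those of Mmp10KO, and 5 and 1661 between the knockouts.

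Leaving out each array in turn, WT at 1 h ran from 218 (without WT_1h replicate 3) to 501, and Mmp10KO at 24 h from 1923 (without Mmp10KO_24h replicate 3) to 6185. Differences of Mmp7KO from WT ran from 0 to 2 (without Mmp10KO_0h replicate 2) at 1 h and from 0 (without WT_0h replicate 1 or WT_24h replicate 3) to 177 (without WT_24h replicate 2) at 24 h. Those of Mmp10KO from WT ran from 3 (without WT_0h replicate 2 or WT_1h replicate 1) to 8 and from 579 (without WT_24h replicate 3) to 1999 (without Mmp10KO_1h replicate 1). Between the knockouts they ran from 1 to 5 (without Mmp7KO_0h replicate 3 or Mmp10KO_0h replicate 2) and from 596 (without Mmp7KO_0h replicate 2) to 1862 (without Mmp10KO_24h replicate 1). The other responses stayed within 1.5 times their counts, at 4621 to 7806 for WT at 24 h, 137 to 226 and 4395 to 5926 for Mmp7KO, and 148 to 276 for Mmp10KO at 1 h. Where 1 array was left in a group, it was assumed to vary like the other groups.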

Other observations

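No explanation was tested in this part. Interferon response genes changed in both directions at 24 h. In WT 13 of 32 rose and 6 fell, 15 and 7 adjusted over the list alone (camera adjusted p = 0.0353, adjusted p = 0.130 with an estimated correlation). The guanylate-binding genes Gbp2 (log2 1.46 ± 0.16 SE, n = 3 and 2) and Gbp3 (1.29 ± 0.17) and the immunoproteasome subunit Psmb8 (0.69 ± 0.10) rose, and the immunity-related GTPase Irgm1 fell by 1.66. In Mmp7KO 15 rose and 2 fell, 15 and 4 adjusted over the list alone (camera adjusted p = 0.000275, adjusted p = 0.0223 with an estimated correlation). Gbp3 rose by 1.57 and Bst2, which tethers viruses, by 1.18, while Irgm1 (-2.21) and the nucleotide kinase Cmpk2 (-0.95) fell. In Mmp10KO 8 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.0906, adjusted p = 0.282 with an estimated correlation). Oasl2 (0.96), Oas2 (0.86) and Irf1 (0.83) rose and Irgm1 fell by 1.62, as did, chosen after their values were seen, Cmpk2 (-0.34) and Irf8 (-0.30). The WT list call ended without WT_24h replicate 2 (adjusted p = 0.116). Calls ended without Mmp10KO_24h replicate 3 for Oas2 (0.50) and without replicate 1 for Cmpk2 (-0.16) and Irf8 (-0.19). That of Irf8 ended in 18 of the 25 fits.

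Metal handling genes passed camera at 24 h in WT and Mmp7KO. In WT 8 of 16 rose and 2 fell, 8 and 3 adjusted over the list alone (camera adjusted p = 0.0167, adjusted p = 0.111 with an estimated correlation). Hmox1, which breaks down heme, rose by 3.92, the metalloreductase Steap4 by 2.78, the metallothionein Mt2 by 1.72 and ceruloplasmin (Cp) by 0.77. The iron sensor Ireb2 (-1.26) and the iron exporter Slc40a1 (-0.60), chosen after their values were seen, fell. In Mmp7KO 9 rose and 2 fell, 10 and 2 adjusted over the list alone (camera adjusted p = 0.000324, adjusted p = 0.0244 with an estimated correlation). Hmox1 rose by 4.95, Steap4 by 2.10, Mt2 by 1.63 and Cp by 0.61, and Ireb2 (-1.17) and Aco1 (-0.48), chosen after their values were seen, fell. The call of Aco1 ended in 6 of the 25 fits that left out 1 array, at -0.47 (adjusted p = 0.0791) without Mmp7KO_24h replicate 1. In Mmp10KO 4 rose, 2 fell and 10 did not pass, 5 and 2 adjusted over the list alone (camera adjusted p = 0.175, adjusted p = 0.367 with an estimated correlation).

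On each array 1 of 4 poly-A spike-in controls stood above the median of its own values over the 25 arrays by 7.003 to 9.76 log2 units more than the next spike-in did. These are relative to each spike-in's own median, as levels are not in the values. An assumed cycle of the spike-ins, counting absent replicates, held for 3 of 8 WT, 9 of 9 Mmp7KO and 8 of 8 Mmp10KO arrays. WT may follow no such cycle, so whether its labels are right stays open. On the largest component of variation WT scored -25.7 to -24.4 at 0 h, -14.6 to 1.16 at 1 h and 49.1 and 52.3 at 24 h, so no WT array lay among those of another time, which says nothing about arrays of the same time. Replicate pairs shared 61 to 166 identical values in WT, 1197 to 2385 in Mmp7KO and 44 to 220 in Mmp10KO, out of 45101 probe sets.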
